A study of Mus musculus with 6 samples.

How the data were processed

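Total RNA from gastrocnemius of 3 Control and 3 Ogg1Tg male mice of a C57BL/6J background was isolated with a column kit and made into libraries with the NuGen Ovation Universal system, per the labels' protocols. The submitters' processing notes name Trimmomatic, SAMtools, HTSeq and the mm10 build, without versions. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. The labels do not mention shared litters or days. The p-values for single genes and single measures reflect the spread between these 6 mice.

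Per the file headers, each deposited file gives 1 library and its class. The file names call the values FPKM, but the deposited values are a signal of another kind: gene counts divided by 1 factor per library. Each value came out as a whole multiple of 1 step per library whatever the length of the gene, within 0.01 of a whole read for 100% of values. For Ogg1Tg replicate 3 the step, 1.006, is close to 1, so its recovery is less distinctive than in the other libraries. The factors that the authors used were 0.778 to 0.838 times the median-of-ratios factors of these 6 libraries, and the step that made them is not given in the sources used here. The design written before the data were examined assumed FPKM. Its test, a linear model on log2 values, was kept because the deposited signal is not a raw count, and tests on recovered reads were added.

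The files hold 37315 entries. Entries without a gene name, 1824 in number, held 2.38% to 3.54% of reads and were left out of the tests. Of 740 such entries past the filter, 0 passed limma, with 56 at an unadjusted p under 0.05. A further 26 symbols had been turned into dates and 13 symbols occurred more than once; these were kept as they stand. Of 35474 symbols, 35320 matched a single gene of GENCODE M21 on GRCm38, the assembly of mm10, which gave the coordinates. Depth in named genes was 45189860 to 56126407 reads. Counting intervals and floors cover counting error only. No pair of libraries agreed within sampling noise: the smallest chi-square per gene between 2 libraries was 13.9.

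Values were transformed as log2(value + 1), which understates the fold of low genes. Genes with a mean of at least 1 over all 6 libraries were tested with limma 3.58.1 in R 4.3.3, with lmFit, a contrast of Ogg1Tg minus Control, eBayes with a variance trend, two-sided moderated tests and Benjamini-Hochberg adjustment, and were called at an adjusted p under 0.05. Single measures were compared with two-sided exact permutation tests. The 30 gene lists with at least 5 tested genes, chosen before the data were examined, were tested with camera at a preset correlation of 0.01, with adjustment over the lists. That preset treats the members of a list as nearly independent, while the correlations estimated from these data ran from -0.0061 to 0.98 over the lists. P-values at the preset therefore rest largely on the spread across genes and do not measure the spread between mice alone. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Markers of substrain and sex were fixed as values to read; the limma p given for Entpd4 comes from the test of all genes and was looked up after its values were seen.

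Genes were named by a rule written before the data were examined. It takes up to 12 higher and 12 lower called genes with the largest absolute log2 fold change whose groups do not overlap, leaving out predicted, Rik, pseudogene and small RNA names. It adds Ogg1, up to 4 called members per list, and for lists described singly without a called member the 2 members with the highest mean. One gene that the rule selects is not reported here. Atf4, Hspa1a, Sesn2, Atf5, Chac1, Irx3 and Entpd4b fall outside it and were chosen after their values were seen. Ratios for genes with 1 to 3 reads in a group use exact binomial limits at 95%, and groups with 0 reads use a floor of 3 reads over the group.

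Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5, median-of-ratios rescaling, quantile normalization, no variance trend, a robust trend, a replicate block, and each library left out in turn with the filter taken on the remaining 5. Added after the data were seen were edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 on recovered reads, edgeR without Ogg1Tg replicate 3, a mean of at least 10 with and without that library, camera with an estimated correlation without it, and each library left out with the filter taken on all 6. The last was added because the count without Ogg1Tg replicate 3 had been seen with both filters and differed. On simulated data with 200 changed genes drawn on these libraries, limma called 85.1% of genes changed 2-fold and 100% of those changed 4-fold, with 11 false calls over 22904 genes. Camera called the shifted list and 0 of 30 unshifted ones. The simulation took means and library sizes from these data, but its spread between mice came from a fixed formula, and its changed genes excluded low ones. It holds no library that stands apart and no correlated list. Its shares therefore need not hold for these data.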

Results

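RNA was sequenced from gastrocnemius, the large calf muscle, of 6 male mice aged 20 weeks on chow. There were 3 Control mice and 3 Ogg1Tg mice, which carry a transgene for the human DNA repair enzyme OGG1 directed to mitochondria. OGG1 removes the oxidised base 8-oxoguanine from DNA. The comparison asks how the muscle transcripts of Ogg1Tg mice differ from those of Control mice. Only gastrocnemius was analysed here. Reads in named genes came to 52070991, 48393073 and 50568308 in Control replicates 1, 2 and 3, and to 56126407, 51651844 and 45189860 in Ogg1Tg replicates 1, 2 and 3. Values below are reads scaled by 1 factor per library, as mean ± SD with n = 3 per group, and fold changes come from log2(value + 1).

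Mouse Ogg1 did not differ between the groups. Its values were 154, 225 and 193 in Control replicates 1, 2 and 3, and 176, 201 and 193 in Ogg1Tg replicates 1, 2 and 3. The log2 fold change was 0.01 ± 0.21 (SE), with a two-sided exact permutation p = 1, where 3 mice against 3 allow no p below 0.1. The gene lies on chromosome 6 from 113326972 to 113335068 of the mm10 build. The transgene is the human sequence and the reads were assigned to mouse genes, so this value does not measure transgene expression. Ddx3y, Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, were expressed in all 6 libraries, with Ddx3y at 4779 ± 416 in Control and 4196 ± 435 in Ogg1Tg muscle. Xist, a transcript of the inactive X chromosome, measured 104 in Control replicate 1 and 2.61 to 16.8 in the other 5 libraries. Nnt, which is disrupted in some C57BL/6 substrains, measured 2317 ± 614 in Control and 2270 ± 862 in Ogg1Tg muscle. Of the other genes read as markers of substrain, Wdfy1 measured 1072 ± 155 and 1069 ± 331, Cyfip2 1068 ± 402 and 1670 ± 765, and Crb1 had a value above 0 in 1 Control library alone. Entpd4 measured 7184 ± 165 and 4161 ± 892, with no overlap between the groups, and did not pass (limma adjusted p = 0.085). Entpd4b, also on chromosome 14, measured 9295 ± 188 and 5291 ± 1137 and did not pass either (limma adjusted p = 0.079).

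Slc7a11, Mthfd2, Asns and Fgf21 were among the genes that rose most in Ogg1Tg muscle. Slc7a11, the cystine transporter, rose from 58.9 ± 6.37 to 2727 ± 256, a fold of 45.6 (limma adjusted p = 1.9e-06). Mthfd2, a mitochondrial enzyme of one-carbon metabolism, rose from 172 ± 11.9 to 5572 ± 1296, a fold of 31.6 (limma adjusted p = 8.5e-06). Asns, asparagine synthetase, rose from 92.3 ± 21.0 to 2691 ± 660 (limma adjusted p = 2.7e-05). Fgf21, a hormone of the response to metabolic stress, had 1 read in the 3 Control libraries together and 2900 in the 3 Ogg1Tg libraries (limma adjusted p = 2.9e-05). After scaling that is a ratio of 2410, with a 95% counting interval from 432 to 95208.

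Across 23312 genes tested with limma, 127 passed an adjusted p of 0.05, of which 92 were higher and 35 lower in Ogg1Tg muscle. At an unadjusted p under 0.05 there were 2570 genes. The count depended on single libraries. It was 43, 42 and 35 without Control replicates 1, 2 and 3, and 62, 194 and 425 without Ogg1Tg replicates 1, 2 and 3. Without Ogg1Tg replicate 3 it was 28 instead of 425 when low genes were filtered on all 6 libraries, a filter that keeps 318 genes at 0 in each of the 5 remaining libraries. With edgeR on the recovered reads 148 genes were called, and with DESeq2 571.

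**Figure D1:**
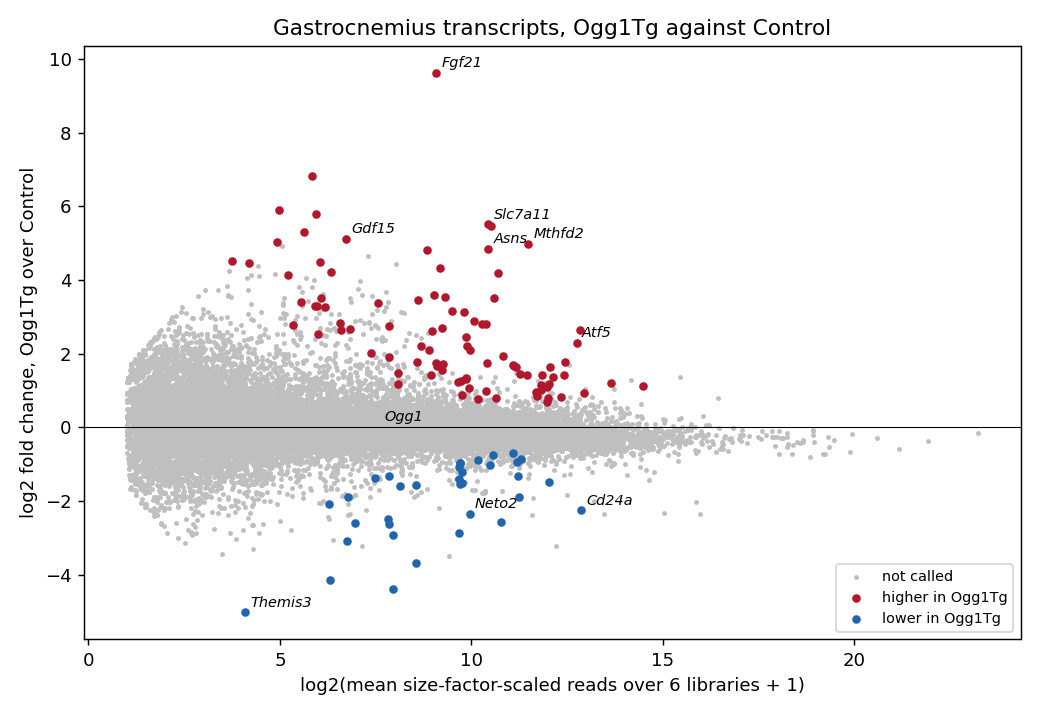
Each point is 1 of 23312 genes, with the log2 of its mean scaled reads over the 6 libraries plus 1 on the x axis and the log2 fold change of Ogg1Tg over Control on the y axis. Red points mark the 92 genes called higher, blue points the 35 called lower and grey points the genes not called by limma; Fgf21 lies highest at 9.62 and Ogg1 at 0.01.

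Psat1, an enzyme of serine synthesis, rose from 69.4 ± 33.8 to 2838 ± 370, a fold of 43.7, and lies on chromosome 19 from 15904678 to 15947337. Gdf15, a secreted stress hormone, rose from 5.03 ± 2.97 to 204 ± 89.9. Trib3, a pseudokinase induced by cellular stress, rose from 52.6 ± 5.68 to 1114 ± 414, a fold of 20.0. Gabrr2, a subunit of GABA receptors, rose from 32.1 ± 11.3 to 888 ± 67.2, a fold of 28.02. Fut1, a fucosyltransferase gene, had 0 reads in Control muscle and 297 in Ogg1Tg muscle, which is at least 82.3-fold higher against a floor of 3 reads over the Control group. On chromosome 7, Fut1 starts at 45617289 on the plus strand and Fgf21 at 45615490 on the minus strand, so the 2 genes run in opposite directions from neighbouring starts. Th, tyrosine hydroxylase, had 1 Control read and a ratio of 129, with a 95% counting interval from 22.8 to 5119. Adm2, a peptide hormone, had 2 Control reads and a ratio of 37.4, with an interval from 10.1 to 313. Mei4, a meiotic recombination gene, rose from 1.80 ± 1.56 to 94.5 ± 22.6. The limma adjusted p of these 8 genes ran from 0.00010 for Gabrr2 to 0.033 for Th.

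Among the genes that fell, Neto2, an auxiliary subunit of glutamate receptors, fell from 1654 ± 143 to 330 ± 80.8 (limma adjusted p = 0.00095). Cd24a, a cell surface glycoprotein, fell from 12176 ± 652 to 2708 ± 1158 (limma adjusted p = 0.0071). Tmem132b fell from 434 ± 131 to 55.8 ± 17.2, Sbk2 from 2983 ± 832 to 511 ± 187, and Igfn1, a gene of skeletal muscle, from 1442 ± 838 to 182 ± 55.2. Slc4a10, a bicarbonate transporter, fell from 190 ± 19.2 to 23.1 ± 11.6. Htra4 fell from 210 ± 29.5 to 36.4 ± 19.1 and Fgfbp3 from 123 ± 10.6 to 29.1 ± 9.22. Themis3 had 71 reads in Control muscle and 0 in Ogg1Tg muscle, which is at least 28.5-fold lower against a floor of 3 reads over the Ogg1Tg group. Cacna2d4, a calcium channel subunit, fell from 462 ± 105 to 27.6 ± 26.7, and Lrtm2, which lies within it on the opposite strand, from 148 ± 26.2 to 8.96 ± 7.36. Irx3os fell from 376 ± 111 to 71.6 ± 41.5 and overlaps Irx3, which was also called lower. Whether the authors' counting used the strand is not given in the sources used here, so reads of such overlapping pairs may be shared. The limma adjusted p of these 12 genes ran from 0.00095 for Neto2 to 0.038 for Irx3os.

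Of the 33 called genes named here, 14 were also called in each of the 6 fits that left out 1 library and filtered on the other 5. These included Fgf21, Fut1, Slc7a11, Psat1, Mthfd2, Asns, Gabrr2, Gdf15, Trib3 and Phgdh among the higher genes, and Neto2 and Tmem132b among the lower ones. Of the 33 genes, 16 were called in 3 or fewer of the 6 fits. Adm2, Ankrd1, Fgfbp3, Htra4, Irx3os, Lrtm2 and Tbc1d1 were called in 2 of them, and Cxcl10 and Th in 1.

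Of 33 tested members of the list of heat shock, unfolded protein and integrated stress response genes, 10 rose, none fell and 23 did not pass. Adjusted over the list alone, 15 rose. The 10 were Fgf21, Psat1, Gdf15, Mthfd2, Asns, Trib3, Phgdh, Sesn2, Atf5 and Chac1, which are known targets or regulators of the integrated stress response. Phgdh, the first enzyme of serine synthesis, rose from 98.8 ± 12.9 to 1164 ± 171 (limma adjusted p = 5.0e-05). Atf4, a transcription factor of that response, measured 4370 ± 205 and 7142 ± 1379 and did not pass (limma adjusted p = 0.14). The heat shock gene Hspa1a measured 754 ± 216 and 593 ± 303. The list passed camera (adjusted p = 3.1e-17 at a preset correlation of 0.01), with adjusted p = 0.51 with an estimated correlation, and passed fry with adjusted p = 0.035.

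**Figure D2:**
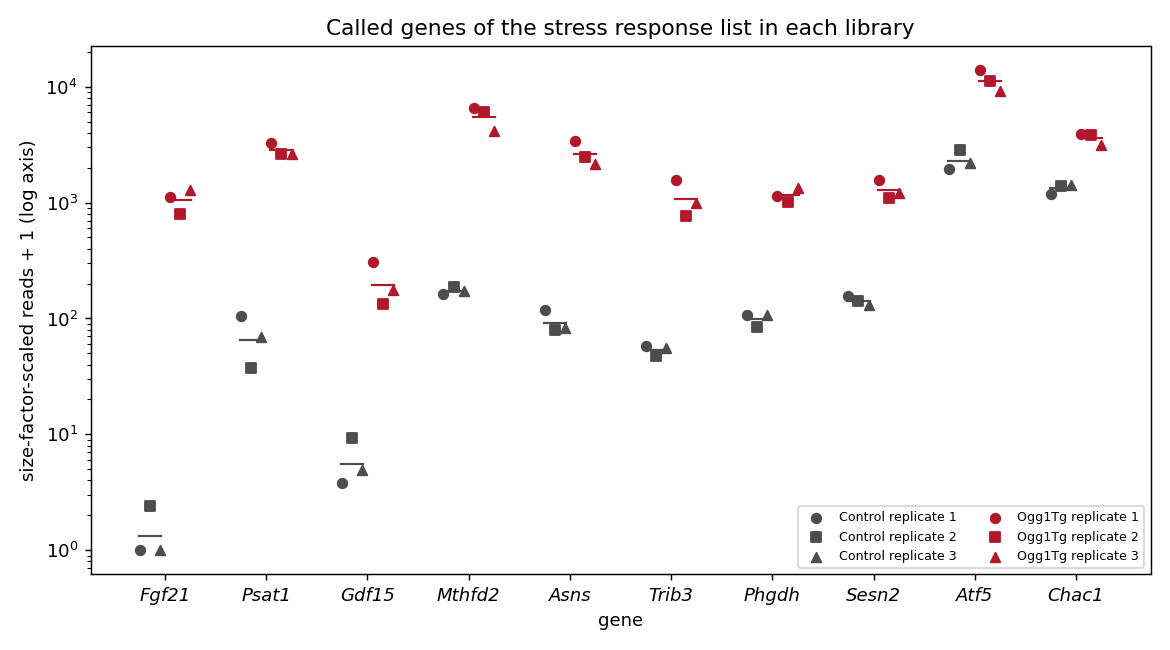
Scaled reads plus 1 on a log axis for the 10 called genes of the stress response list, in the 3 Control libraries (grey) and the 3 Ogg1Tg libraries (red), with the marker giving the replicate and the horizontal line the mean of the log values. For each gene the 3 Ogg1Tg libraries lie above the 3 Control libraries; the smallest fitted log2 fold change is 1.44, for Chac1.

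Cytosolic ribosomal protein genes lay slightly higher in Ogg1Tg muscle, with 43 of 44 members above 0 and a median log2 fold change of 0.37. None of the 44 passed over all genes, and 32 rose when adjusted over the list alone. Rpl4 measured 20362 ± 2293 and 24459 ± 3608, and Rps2 29145 ± 2727 and 26515 ± 7779. The list passed camera (adjusted p = 7.9e-25), with adjusted p = 0.51 with an estimated correlation. Slow-twitch fibre genes had a median log2 fold change of 0.76, with 13 of 14 members above 0. None of the 14 passed over all genes, and 7 rose when adjusted over the list alone. Myh7, the slow myosin heavy chain, measured 10585, 35642 and 35632 in the Control libraries and 57593, 79545 and 50855 in the Ogg1Tg libraries. The slow-twitch list passed camera (adjusted p = 3.9e-07), with adjusted p = 0.63 with an estimated correlation. Its median in Control replicate 1 was -0.65 from the Control mean. Fast-twitch fibre genes had a median of -0.39, and of -0.13 without Ogg1Tg replicate 3, with none of 16 members above 0 and none passing. That list did not pass camera (adjusted p = 0.090), with adjusted p = 0.87 with an estimated correlation. It passed, lower in Ogg1Tg muscle, with median-of-ratios rescaling, with no variance trend and without Ogg1Tg replicate 2 (camera adjusted p = 0.049, 0.019 and 0.0060), and not without Ogg1Tg replicate 3 (adjusted p = 0.68).

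Ogg1Tg replicate 3 stood apart from the other libraries. Its Spearman correlation with each of the others across genes was 0.946 to 0.953, against 0.975 to 0.983 among the other 5, and the first principal component, with 42.5% of the variance, separated it. Neutrophil and lymphocyte markers had a median log2 difference from the Control mean of 6.11 in that library, and of 0.70 and 0.44 in Ogg1Tg replicates 1 and 2. None of the 14 tested members passed. In the same library adipocyte markers had a median of 1.93 and macrophage genes one of 1.13, against -0.10 and -0.26, and -0.34 and -0.51, in Ogg1Tg replicates 1 and 2. Neither list passed with all 6 libraries (camera adjusted p = 0.10 and 0.39). Igkc averaged 23.2 ± 9.92 in Control and 730 ± 1210 in Ogg1Tg muscle. Ighm measured 312, 544 and 6308 in Ogg1Tg replicates 1, 2 and 3, against 3866 ± 286 in Control. The list passed camera (adjusted p = 0.0014), with adjusted p = 0.87 with an estimated correlation, and did not pass without Ogg1Tg replicate 3 (adjusted p = 0.68).

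Genes of energy metabolism had lower medians in the Ogg1Tg group, in large part through Ogg1Tg replicate 3. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of -0.33, and 56 of the 57 tested lay below 0. The median of that list was 0.02, -0.23 and -0.77 in Ogg1Tg replicates 1, 2 and 3. Without replicate 3 it was -0.09. Atp5b, the beta subunit of ATP synthase, measured 78453 ± 3611 and 70951 ± 18264. The 13 mRNAs of mitochondrial DNA had a median of -0.59, and of -0.30 without Ogg1Tg replicate 3. They took 12.7% ± 1.25 of reads in Control and 10.03% ± 1.63 in Ogg1Tg muscle (two-sided exact permutation p = 0.2, n = 3). The tricarboxylic acid cycle list had a median of -0.32, and of -0.13 without Ogg1Tg replicate 3, with Ogdh, a subunit of the oxoglutarate dehydrogenase complex, at 48496 ± 1982 and 39893 ± 10597. The glycolysis and glycogen list had a median of -0.39, and of -0.12 without that library, with Aldoa at 457094 ± 64270 and 369648 ± 114486. In Ogg1Tg replicates 1, 2 and 3 the tricarboxylic acid cycle list lay at -0.04, -0.29 and -0.75, against -0.03 to 0.05 in Control. The glycolysis list lay at -0.26, 0.02 and -0.86, against -0.14 to 0.22 in Control. No member of these 4 lists passed limma, over all genes or adjusted over the list alone. The camera adjusted p was 4.2e-10 for oxidative phosphorylation, 0.0054 for mitochondrial mRNAs, 4.2e-05 for the tricarboxylic acid cycle and 0.0024 for glycolysis, with adjusted p = 0.87 with an estimated correlation for each. Glycolysis did not pass camera without Ogg1Tg replicate 3 or with quantile normalization (adjusted p = 0.073 and 0.18).

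**Figure D3:**
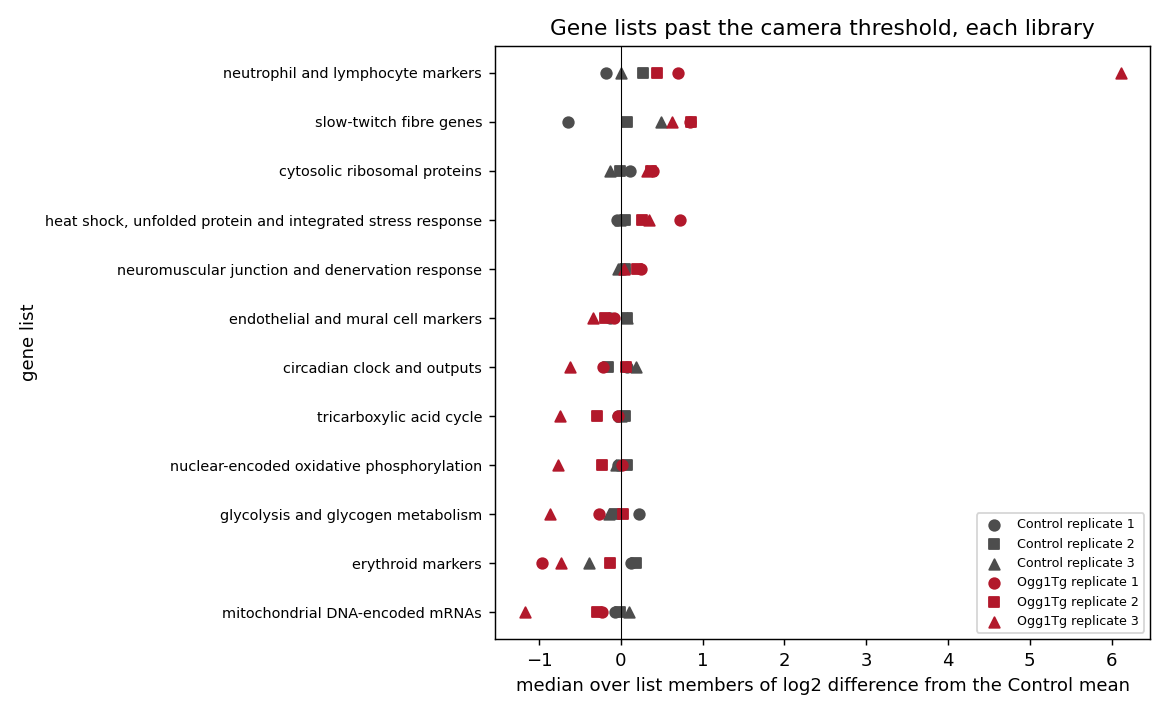
Median over the members of each gene list of the log2 difference from the Control mean (x axis) in the 3 Control libraries (grey) and the 3 Ogg1Tg libraries (red), with the marker giving the replicate, for the 12 lists that passed camera at the preset correlation. Ogg1Tg replicate 3 reaches 6.11 in the neutrophil and lymphocyte list and -1.18 in the mitochondrial mRNAs.

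Another 4 of the 30 lists passed camera. Neuromuscular junction genes had a median of 0.06 and a mean of 0.33, with 1 of 18 members called over all genes and 5 adjusted over the list alone (camera adjusted p = 0.010). The called member was Gadd45a, a stress-induced gene, which rose from 244 ± 15.7 to 1916 ± 713. Erythroid markers had a median of -0.58, with none of 8 members called over all genes and 3 lower adjusted over the list alone (camera adjusted p = 0.0049). Alas2 measured 469 ± 54.5 and 410 ± 19.6. Endothelial and mural cell markers had a median of -0.22, and circadian clock genes one of -0.24, with no member called in either list (camera adjusted p = 0.0090 and 0.012). With an estimated correlation the adjusted p = 0.51 for the neuromuscular list, 0.60 for erythroid markers, and 0.87 for the endothelial and circadian lists. The neuromuscular list did not pass camera without Ogg1Tg replicate 1 (adjusted p = 0.11). The endothelial list did not pass without Control replicate 2, Control replicate 3 or Ogg1Tg replicate 3 (camera adjusted p = 0.094, 0.062 and 0.073), nor the circadian list without Control replicate 3 or Ogg1Tg replicate 3 (camera adjusted p = 0.093 and 0.56). With quantile normalization neither the endothelial nor the circadian list passed (camera adjusted p = 0.12 and 0.094).

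Of the DNA repair list 2 members passed singly, neither of them a repair enzyme, and no antioxidant genes did. Of 32 tested members of the base excision and other DNA repair list, 2 rose, over all genes and adjusted over the list alone, and the list did not pass camera (adjusted p = 0.068). The 2 were Gadd45a and Cdkn1a, an inhibitor of the cell cycle, which rose from 612 ± 64.7 to 2125 ± 792. The list passed, higher in Ogg1Tg muscle, without Ogg1Tg replicate 3 and with median-of-ratios rescaling (camera adjusted p = 0.022 and 0.037). None of 32 antioxidant and redox genes passed, and the list's median was -0.02 (camera adjusted p = 0.51). Without Ogg1Tg replicate 3 that list passed, higher in Ogg1Tg muscle, with a median of 0.096 (camera adjusted p = 0.030). Without that library the DNA repair and antioxidant lists had adjusted p = 0.43 and 0.68 with an estimated correlation. Sod2, the mitochondrial superoxide dismutase, measured 17132 ± 639 and 12733 ± 3344. None of 35 genes of mitochondrial biogenesis, DNA maintenance and dynamics passed (camera adjusted p = 0.056). That list passed, lower in Ogg1Tg muscle, with no filter, with the replicate block and without Ogg1Tg replicate 1 or 2 (camera adjusted p = 0.036, 0.034, 0.00042 and 0.019), and did not pass without Ogg1Tg replicate 3 (adjusted p = 0.68). It had adjusted p = 0.87 with an estimated correlation.

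Single genes were called in lists that did not pass. Acot2, a mitochondrial acyl-CoA thioesterase, rose from 1002 ± 186 to 3321 ± 1089. Tbc1d1, a regulator of glucose transporter traffic, fell from 6096 ± 782 to 2266 ± 772. Ankrd1 and Actc1, of the myogenesis and regeneration list, rose from 291 ± 57.3 to 2200 ± 1116 and from 2045 ± 973 to 12581 ± 5544. Myc rose from 247 ± 28.8 to 830 ± 4.26, and the chemokine gene Cxcl10 from 18.1 ± 6.01 to 107 ± 28.7. The limma adjusted p of these 6 genes ran from 0.0010 for Myc to 0.039 for Tbc1d1.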

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

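Tests on recovered reads and each fit described as added were chosen after the data were seen. The total of 127 genes lay between 102 and 177 with a pseudocount of 0.1, no filter, a mean of at least 5 or 10, either rescaling, a robust trend, the replicate block or edgeR, and all 127 kept their direction in each planned fit. Without a variance trend 46 genes passed, 41 higher and 5 lower, 27 of them among the 127. With 1 library left out the total ran from 35 to 425, with 32 to 225 higher and 2 to 200 lower. The lowest was without Control replicate 3 and the highest without Ogg1Tg replicate 3. Filtering on all 6 libraries instead gave 32, 38 and 22 without Control replicates 1, 2 and 3, 41 and 152 without Ogg1Tg replicates 1 and 2, and 28 without Ogg1Tg replicate 3. The last gap, 28 against 425, comes with 318 genes that are 0 in the other 5 libraries. They entered the variance trend with no variance, and the prior degrees of freedom were 1.42 with them and 6.93 without. The filter on the remaining 5 libraries was preferred after both counts had been seen. An added mean of at least 10 without that library gave 419, 218 higher and 201 lower, and edgeR without it 362, 246 higher and 116 lower. DESeq2 gave 571, 326 higher and 245 lower; the cause was not tested. With the preset correlation 11 to 17 lists passed, but not the same ones: without Ogg1Tg replicate 3, 15 passed, of which 8 were among the 12 and 7 were not. Glycolysis, lymphocyte, endothelial and circadian lists no longer passed. DNA repair, antioxidant, mitochondrial ribosome and Schwann cell lists then passed as higher, and lipid synthesis, interferon and macrophage lists as lower. Macrophage genes passed as higher without Ogg1Tg replicate 1 or 2, and the mitochondrial ribosome as lower without replicate 1. Among the other gains were fast-twitch, fatty acid and tendon lists, all lower. Quantile normalization lost glycolysis, endothelial and circadian lists and gained adipocyte and extracellular matrix lists as higher. With other set tests, 0 passed with an estimated correlation, 0 with it without Ogg1Tg replicate 3, and 1 with fry. The replicate block gave 102 genes and 13 lists, and the numbers do not pair the mice, since the correlations of same-numbered deviations were -0.05, -0.01 and 0.03. Between-group variance was 23.2% to 33.5% in each planned fit. With all 6 libraries and the main settings it was 25.1%, against 18.4% to 21.0% for the other splits of the libraries into 3 against 3. Ogg1 was called in no fit, and its log2 fold change ran from -0.14 to 0.14 over the left-out libraries, -0.068 under quantile normalization and -0.0049 with a mean of at least 10 without Ogg1Tg replicate 3. No called gene changed direction. Among genes not called, quantile normalization turned Atp5b to 0.090, Aldoa to 0.056, Pygm to 0.053 and Rps2 to 0.16. Over the left-out libraries Atp5b ran from -0.35 to 0.033, Rps2 from -0.39 to 0.036 and Vwf from -0.067 to 0.12. Without Ogg1Tg replicate 3, the mean of at least 10 gave Atp5b 0.033 and Rps2 0.036, and edgeR gave Atp5b 0.081, Pygm 0.021 and Rps2 0.090. Of 33 named called genes, 13 stayed called without a variance trend and 15 to 33 with 1 library left out.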

Other observations

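Further gene groups were compared after the called genes had been seen, so their counts are not independent evidence. Of 27 amino acid transporter genes, 7 were higher in Ogg1Tg muscle, over all genes and adjusted over the list alone. Slc7a5, a transporter of large neutral amino acids, rose from 171 ± 31.8 to 3131 ± 572, and Slc7a1, a transporter of cationic amino acids, from 339 ± 57.5 to 2352 ± 417 (limma adjusted p = 2.7e-05 and 0.00014). Of 21 genes of serine, glycine, one-carbon and proline synthesis, 8 were higher, and 10 adjusted over the list alone. Aldh18a1 and Pycr1, enzymes of proline synthesis, rose from 251 ± 49.8 to 2858 ± 605 and from 142 ± 4.97 to 870 ± 77.5 (limma adjusted p = 8.5e-05 and 9.9e-05). Of the 13 integrated stress response members of the stress list, 10 were higher over all genes, with a median log2 fold change of 3.54. Of its other 20 members, which are heat shock proteins, chaperones and the transcription factors Hsf1, Hsf2, Xbp1 and Atf6, none was called over all genes. Adjusted over those 20 alone 1 was higher, and their median was 0.05.

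Cytosolic aminoacyl-tRNA synthetase genes may have been higher where the mitochondrial ones were not, a hypothesis formed and tested on these data after the result was seen. Of 20 cytosolic genes, 4 were called higher and 12 adjusted over the list alone, with a median log2 fold change of 0.50, above each of 10000 random lists matched on mean value, and medians of 0.68, 0.51 and 0.23 in Ogg1Tg replicates 1, 2 and 3, against at most 0.066 in Control. Gars rose from 2945 ± 178 to 8037 ± 1888 and Sars from 2376 ± 192 to 4819 ± 842 (limma adjusted p = 0.010 and 0.029). Gars and Kars, counted here as cytosolic, encode the mitochondrial enzymes as well, so the lists do not fully separate the compartments. Kars had a log2 fold change of -0.01. The median of 17 mitochondrial genes, -0.10, lay at percentile 22.36 of such lists, and none of them was called. The difference between the lists was not tested across mice.

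For the 10 called stress genes, tests of tissue mixed into Ogg1Tg replicate 3 and of library scaling were chosen after the result was seen, the first with its cutoff of 5 members set when its counts were known. Without that library limma called 14 of the 33 list members higher, or 6 with the filter on all 6 libraries, which argues against it as the source. The log2 median-of-ratios factors ranged over 0.11, against a smallest log2 fold change of 1.44 among the 10 genes, which argues against scaling. An effect of the genotype may account for the pattern, as a hypothesis. Litter, cage and feeding state were not given in the labels and stay open. Whether the groups differ in substrain was not tested and also stays open. Among its markers Entpd4 did not overlap between the groups, though it did not pass, while Nnt, Wdfy1 and Cyfip2 overlapped.

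For the lymphocyte transcripts of Ogg1Tg replicate 3, the test of a shared immune response and the tests of dilution were chosen after the result was seen. The B lymphocyte list had medians of 0.62 and -0.18 in Ogg1Tg replicates 1 and 2 and of 6.99 in replicate 3. The T lymphocyte list had medians of 0.21, -0.0037 and 5.62 in the same libraries. These values argue against a response of the size seen in replicate 3 being shared by the genotype. A smaller shared rise stays open: the neutrophil and lymphocyte list lay at 0.70 and 0.44 in Ogg1Tg replicates 1 and 2, against at most 0.27 in Control. Lymph node tissue in the sample is a candidate explanation that stays open. Of 7 genes of lymph node stroma and high endothelial venules, 3 were 8-fold or more above the highest other library. They were Cxcl13 at 463, Glycam1 at 281 and Chst4 at 29.2, fewer than the test asked for. The highest other library was taken as at least 3. Madcam1, at 11.1 in Ogg1Tg replicate 3 and 0 in each other library, could not reach 8-fold over that floor, so the outcome of the test depended on it. Adipocyte and macrophage lists also lay higher in Ogg1Tg replicate 3, at 1.93 and 1.13. Dilution of fibre RNA there stays open for the lists of oxidative phosphorylation and of mitochondrial mRNAs, with medians of -0.092 and -0.30 without that library: fast-twitch genes lay at -0.87 there, against -0.27 and 0.13 in Ogg1Tg replicates 1 and 2, and slow-twitch genes at 0.63, against 0.84 and 0.86, while the fibre transcript Ttn took 15.1% of its reads, within the Control range of 14.2% to 15.5%. Mitochondrial mRNAs also lay at -0.24 and -0.29 in Ogg1Tg replicates 1 and 2, below each Control, but their share of reads was 11.5% in Ogg1Tg replicate 1 and 11.3% in Control replicate 1, so how far their difference reaches beyond that library stays open.

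For the higher ribosomal protein list, the test of tissue in Ogg1Tg replicate 3 was chosen after the result was seen, as were the requirement on each library in the test of terminal oligopyrimidine mRNAs and the reading of direction in the test of gene length. The median without that library was 0.38, which argues against it as the source. Random lists matched on exonic length and mean value had medians centred on -0.19, against 0.37 for the list, which lay at percentile 100 of them; the opposite direction argues against gene length. The list of 21 other mRNAs with a terminal oligopyrimidine tract lay at percentile 100 of lists matched on mean value, with a median of 0.14 and 7 members higher adjusted over it alone, but its median in Ogg1Tg replicate 3 was 0.02, within the Control range of -0.06 to 0.08. The 20 stress-list members outside the integrated stress response lay at percentile 99.79 of their own random lists with none called. Such percentiles therefore separate lists weakly, and a change shared by mRNAs with a terminal oligopyrimidine tract stays open.

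The 10 splits of the 6 libraries into 3 against 3 are too few for a share under 0.05. The real split gave 127 genes and was the 1 split with as many, and the highest of the others gave 0. For the lists, the real split gave 12, the highest of the others gave 20, and 10 of the 10 splits gave at least as many as the real one. The number of lists past camera at the preset correlation therefore did not set the genotypes apart. As a search for the transgene's insertion, called genes were counted in windows of 5 Mb. The densest held 4 of them, and the median of 10000 random draws was also 4. In 1 such window, on chromosome 7, the starts of Atf5, Fgf21, Fut1 and Slc17a7 ran from 44812256 to 45617289. In another, on chromosome 19, those of Aldh18a1, Ankrd1, Btaf1 and Fgfbp3 ran from 36111961 to 40550257. A count over 5 Mb cannot detect an effect on few neighbouring genes, so an effect of the insertion stays open.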
